A study of Arabidopsis thaliana with 14 samples.

How the data were processed

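Pre-globular seeds of Arabidopsis thaliana Ws-0 plants 38 to 46 days old, grown at 20 °C under continuous light, were fixed in ethanol and acetic acid and embedded in paraffin, per the labels' protocols. Siliques measured 1 to 1.1 cm. Compartments and sections of whole seeds were freed with a laser microdissection microscope, and 2 to 5 ng of total RNA were amplified, labelled with biotin and hybridized to ATH1 arrays. The labels name 2 biological replicates for each of 7 groups, which gave 14 arrays, and they do not tie single plants to the regions. The groups were taken from the sample labels.

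The deposited values were intensity values on a linear scale, 1 for each probe set on each array. Per the submitters' processing notes the tool was GCOS, and its version and algorithm were not given in the sources used here. The values themselves showed the scaling, since the mean after leaving out the lowest and highest 2% of values was 500.04 to 500.07 on every array. The array medians were 132 and 133 in the embryo proper, 136 and 160 in the micropylar, 127 and 110.4 in the peripheral and 131 and 126 in the chalazal endosperm. They were 146 and 147 in the general seed coat, 155 and 149 in the chalazal seed coat and 179 and 176 in the whole seed. Detection calls were not used here. The number of arrays limits the precision of every value.

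The table held 22810 probe sets, of which 64 controls were left out of the tests. Values were used as scaled by the submitters and turned into log2(value + 35.9231), where the added value is the 25th percentile of all values. A probe set was tested where both arrays of at least 1 group lay above that array's 40th percentile, which left 17336 of 22746. The annotation of the platform gave 1 gene symbol for 13513 probe sets, several for 503 and none for 8730, and of the tested probe sets 7061 had none and 384 had several. Of the single-gene probe sets, 13436 matched the TAIR10.1 gene table by gene ID and 77 did not, and that table was used for names and for which genes neighbour each other. The named probe sets covered 13355 genes, of which 9763 were tested. Where a gene had several probe sets, the one with the highest mean was used. Of 116 genes with several tested probe sets, 93 had some difference in call between them and 1, AT5G22700, had opposite calls.

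A linear model with a mean for each of the 7 groups was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend on mean signal (7 residual and 13.4 prior degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method within each of 13 comparisons. Each compartment was set against the mean of the other 5, and a stricter count took probe sets that passed against each of the other 5 singly. Further comparisons were endosperm against seed coat, the 3 pairs of endosperm regions, the chalazal against the general seed coat, the whole seed against the mean of the 6 compartments, and the interaction of the chalazal differences in endosperm and seed coat. A probe set was called higher or lower at an adjusted p under 0.05 and a difference of at least 2-fold. The tests are two-sided. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

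A set of 14 gene lists was fixed before the data were examined, as were the comparisons, the filter, the alternatives and the rule for named genes. The lists held early embryo regulators, suspensor genes, endosperm regulators and imprinted genes, type I MADS-box genes, cytokinin, gibberellin, auxin and flavonoid genes, seed coat genes, vascular and transport genes, cell cycle, photosynthesis, seed maturation and heat shock genes. Of 311 listed genes, 51 had a named probe set and 42 were tested. Lists with at least 5 tested genes were set against all other genes with camera (preset correlation 0.01) and tested with fry, over a family of 20 tests. The type I MADS-box list (16 of 29 tested) and the photosynthesis list (7 of 38) met that limit, and the other lists were counted only. A further 26 gene families were formed after the probe annotation was seen.

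The rule for named genes took, for each compartment, the 8 largest increases among called genes whose arrays both lay above all 10 other compartment arrays, the 3 largest decreases likewise below them, and up to 4 called members of each list by smallest adjusted p. For the other comparisons it took the 6 largest increases and the 6 largest decreases whose arrays did not overlap, or for the interaction those called, and the same list members. A set of 31 genes could be named whatever their result, and 3 of them were tested (AGL62, BAN and RR22).

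The fit was tested on simulated data with 17336 probe sets, of which 67, 67 and 66 were changed 2-fold, 4-fold and 8-fold. Each probe set had the same spread in all groups and was drawn independently of the others. The shares called therefore need not hold for groups with looser replicates or where more probe sets change. The simulated list tests do not cover correlated genes. For the chalazal endosperm against the other 5 compartments, 2.99%, 53.7% and 90.9% of these were called. For the chalazal against the general seed coat the shares were 2.99%, 32.8% and 54.5%, and for the whole seed 10.4%, 55.2% and 80.3%. No call had the wrong sign, and 1, 4 and 5 unchanged probe sets were called in these comparisons. For the list test, 16 further probe sets were all raised 2-fold. That list gave a camera p of 4.32e-14, 4.47e-13 and 3.48e-13, and a list of 16 unchanged ones 0.568, 0.440 and 0.899.

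The alternatives were quantile normalization, no pseudocount, no filter on dim probe sets, no trend in the variances, array weights, the replicate number as a block, only the groups compared in the fit, and each array left out in turn. A fit without all micropylar and chalazal endosperm arrays was added after the spread of their replicates was seen.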

Results

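The data described 7 kinds of sample from young Arabidopsis thaliana seeds of the Ws-0 accession, in which the embryo proper held 2 to 8 cells. Laser capture microdissection, in which a laser frees chosen tissue from a section, gave 6 compartments. These were the embryo proper, 3 regions of the endosperm (the nourishing tissue that grows beside the embryo) and 2 regions of the maternal seed coat. The micropylar endosperm surrounds the embryo, the chalazal endosperm lies at the opposite pole beside the tissue that supplies the seed, and the peripheral endosperm lies between them. The peripheral endosperm carried that name in the sample titles, while its source label called it cellularized endosperm. Sections of whole seeds formed the 7th group. Each group had 2 arrays, so the 14 arrays limit the precision of each value. The design asked how the compartments differ from one another and what a whole-seed sample shows of them.

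Values are signal on the array's linear scale, given as mean ± SD with n = 2 arrays per group, and differences are on the log2(signal + 35.9) scale with their standard error (SE). Where 1 side lies under 35.9 the size of a difference depends on that added value. Of 22746 non-control probe sets, 17336 were bright enough to be tested. The 2 arrays of a group correlated at r = 0.930 in the embryo proper, 0.924 in the peripheral endosperm, 0.912 in the general seed coat, 0.915 in the chalazal seed coat and 0.900 in the whole seed. The correlation was lower in the micropylar endosperm (0.858) and the chalazal endosperm (0.852), where the SD between replicates was 0.76 and 0.78 on the log2 scale, against 0.52 to 0.57 in the other 5 groups. The same 2 regions had the brightest control spots, with a spike-in mean of 86690 in the micropylar and 66748 in the chalazal endosperm, against 31894.5 to 46075 elsewhere. These correlations are across probe sets, which are not independent replicates.

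Along the first principal component of the 14 arrays (32.8% of the variance) the arrays of the 3 endosperm regions and of the seed coat lay apart, and the second component held 20.8%. Group means of the micropylar and peripheral endosperm correlated at 0.813 and those of the general and chalazal seed coat at 0.802. The whole seed correlated most with the general seed coat (0.897), and the chalazal endosperm and the general seed coat had the lowest correlation of any pair of groups (0.544).

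**Figure D1:**
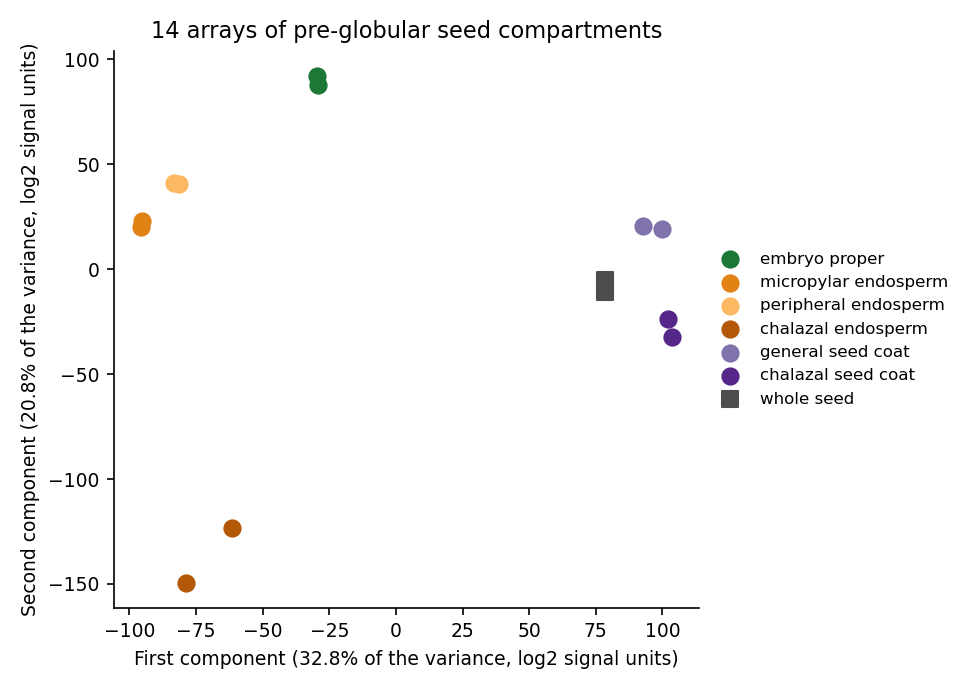
Each point is 1 of the 14 arrays, placed by its scores on the first component (32.8% of the variance, x axis) and the second component (20.8%, y axis) of the tested log2 values, coloured by group. The whole-seed arrays lie near those of both seed coat regions.

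The embryo proper had higher signal than the mean of the other 5 compartments for 2290 probe sets and lower signal for 2104. AT3G24250 was higher by 6.37 (SE 0.47, adjusted p = 2.93e-08), with a signal of 15036 ± 1120 in the embryo proper and 36.7 ± 15.0 in the peripheral endosperm. AT5G38170 was higher by 6.08 and TRM28, a member of a family of TON1-recruiting proteins, by 5.61 (4834 ± 1153). BABY BOOM (BBM), a transcription factor that promotes embryo formation, was higher by 3.31 (SE 0.52, adjusted p = 8.72e-05), at 630.5 ± 70.4 against 8.54 ± 0.162 in the chalazal seed coat. AT1G12180 was lower by a log2 difference of -5.65, with 15.1 ± 4.63 in the embryo proper and 62657 ± 9184 in the chalazal endosperm.

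Among the gene lists chosen before the data were examined, all 3 tested cell cycle genes were higher in the embryo proper. Aurora kinase AUR2 was higher by 2.26 (SE 0.47, adjusted p = 0.00127), PROLIFERA (PRL), a subunit of the replication helicase, by 1.59 (SE 0.34, adjusted p = 0.00131), and AUR1 by 2.39 (adjusted p = 0.00103). The call for AUR1 was lost without embryo proper replicate 1 (adjusted p = 0.0562, with a range of 0.000155 to 0.0562 over 17 alternative fits). Of 16 type I MADS-box genes, a transcription factor class with many members active in endosperm, none was higher and 7 were lower, the same number as adjusted over the list alone. AGL62, which delays the forming of cell walls in the endosperm, was lower there by -2.53 (SE 0.38). As a group these genes stood below other genes (camera adjusted p = 0.00402). Of 7 photosynthesis genes, 5 were lower, also adjusted over the list alone (camera adjusted p = 0.000536), among them the photosystem II gene PSBY at -1.73 (SE 0.28).

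All other lists had under 5 tested genes and so received counts and no set test. BBM rose and PHV did not pass the test among the early embryo regulators. Of the 2 cytokinin genes, the response regulator ARR15 was higher (267 ± 23.5) and RR22 lower. Of the 4 YUCCA genes of auxin synthesis, YUC4 was higher by 2.27 (SE 0.47) and YUC6 lower. The calls of ARR15, YUC6 and RR22 were lost in 3, 3 and 1 of 17 alternative fits (largest adjusted p 0.0759, 0.134 and 0.179). The flavonoid genes DFR and BAN, which encode reductases on the path to proanthocyanidins, were lower by -3.49 (SE 0.32) and -2.88 (SE 0.47), while UGT80B1 was not called. AGL62 was the 1 endosperm regulator called lower of 3 tested (2 adjusted over the list alone). The single tested heat shock gene, AT1G53540, had a difference of 1.78 (SE 0.62, adjusted p = 0.0385), and over 17 alternative fits its adjusted p ranged from 0.00476 to 0.403 and its call was lost in 7. The lists for the suspensor, gibberellin metabolism, vascular tissue and seed maturation had 0 tested genes. With 1 embryo proper array left, the total of 4394 calls dropped to 2250 without replicate 1 and 2065 without replicate 2.

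The micropylar endosperm was higher than the mean of the other 5 compartments for 1709 probe sets and lower for 1988. AT4G23080 was higher by 7.50 (SE 0.51, adjusted p = 1.31e-09), with 24888 ± 4145 in the micropylar endosperm and 92.3 ± 117 in the peripheral endosperm. TBL15, of a family that acetylates cell wall polysaccharides, was higher by 6.89 and reached 51091 ± 1727. Type I MADS-box genes were among the increases, with AGL96 higher by 5.90 (SE 0.49, 13957 ± 686), AGL57 by 5.72 (SE 0.46, 5686 ± 171), AGL48 by 5.23 (SE 0.44, 5195 ± 726) and AGL95 by 3.20 (SE 0.55). AT1G78170 was lower by -4.38 (SE 0.36), at 7.20 ± 2.97 against 6074 ± 1108 in the general seed coat.

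Across all 16 type I MADS-box genes, 5 were higher and 2 lower in the micropylar endosperm, with the same counts adjusted over the list alone. The median difference was -0.05 while the mean was 0.99 and the set test pointed up, so the list did not move as a whole (camera adjusted p = 0.0688). Of 7 photosynthesis genes, 4 were higher and none lower, also adjusted over the list alone (camera adjusted p = 0.000483), led by the photosystem genes PSBW at 2.22 (SE 0.25) and PSAE-1 at 2.70 (SE 0.36). Of the 4 auxin genes YUC11 was higher by 2.19 (SE 0.43, 442 ± 158) and YUC6 lower by -1.42 (SE 0.49), a call lost in 9 of 17 alternative fits (adjusted p from 0.0203 to 0.405). ARA12, a subtilase needed for mucilage release from the seed coat, was lower by -2.42 (SE 0.48). Without micropylar endosperm replicate 2 the total of 3697 calls dropped to 2108, and this group had the second loosest replicates.

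**Figure D2:**
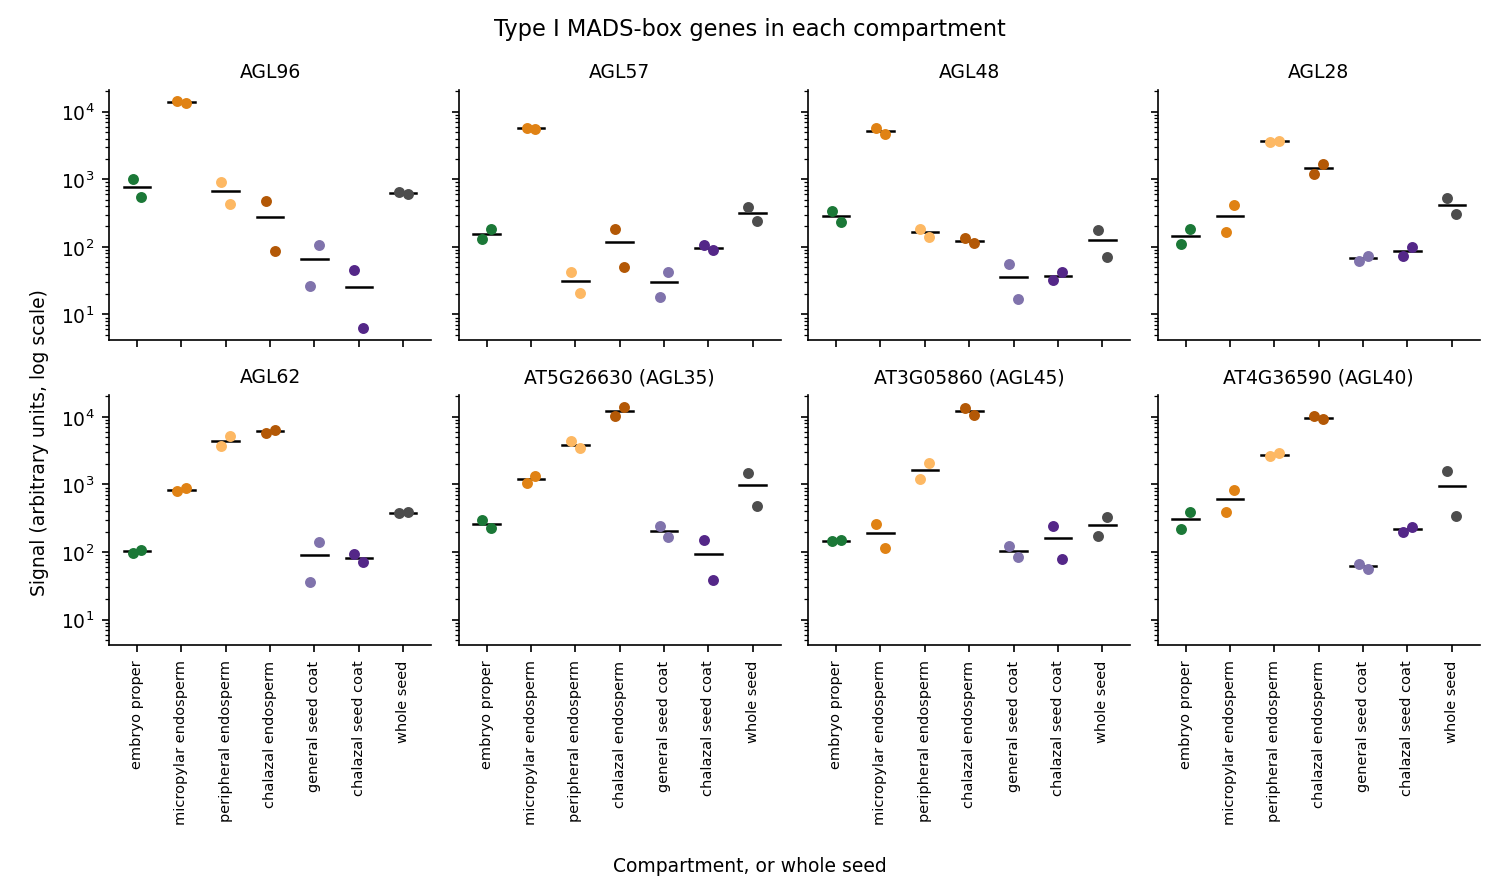
Each panel shows the signal (log axis) of 1 type I MADS-box gene across the 6 compartments and the whole seed, with points for the 2 arrays and a line at their mean. AGL96, AGL57 and AGL48 are brightest in the micropylar endosperm (13957, 5686 and 5195), AGL28 in the peripheral endosperm (3636), and AGL62, AT5G26630, AT3G05860 and AT4G36590 in the chalazal endosperm (6160, 12069, 12167 and 9772).

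In the peripheral endosperm, 1763 probe sets were higher than the mean of the other 5 compartments and 1956 lower. All 7 photosynthesis genes tested were higher, also adjusted over the list alone, with a median difference of 2.84 (camera adjusted p = 1.42e-10). PSAN of photosystem I was higher by 4.42 (SE 0.53, 4281 ± 1272), PSAE-1 by 3.47 (SE 0.36, 10172 ± 1257), Rubisco activase (RCA) by 2.84 (SE 0.38, 2161 ± 268) and PSBW by 2.48 (SE 0.25, 10502 ± 720). Each of the 7 had its brightest compartment mean in the peripheral endosperm. AT3G24790 (5.29, SE 0.52) and AT3G17080 (5.02, SE 0.44) were among the genes with the largest increases, and NET4B, an actin-binding protein, was lower by -4.42 (SE 0.46).

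**Figure D3:**
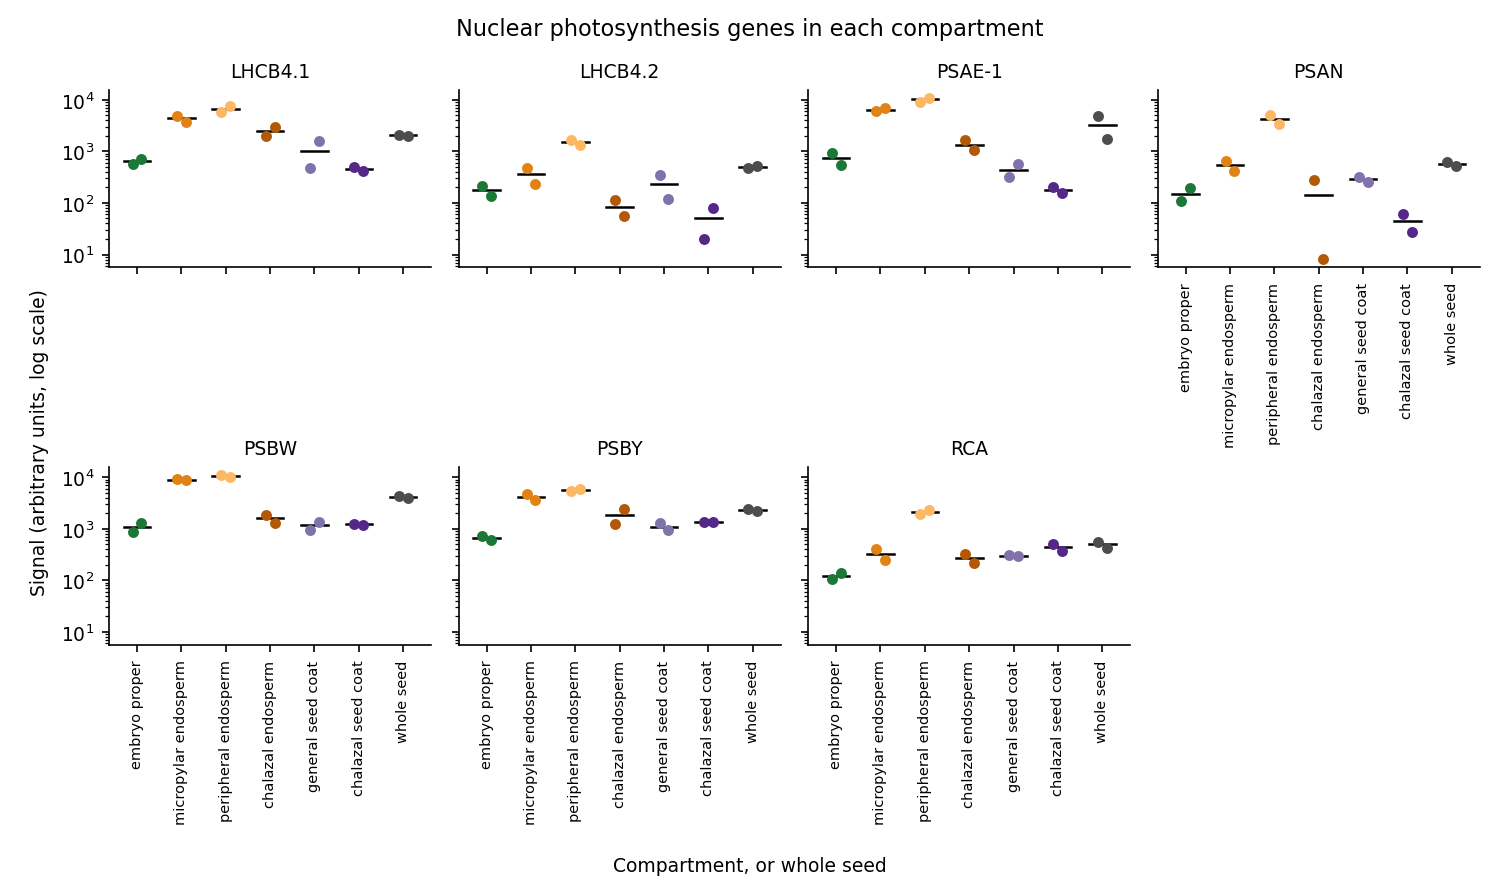
Mean signal (log axis) of 7 photosynthesis genes across the 6 compartments and the whole seed, with a point for each of the 2 arrays. All 7 genes are brightest in the peripheral endosperm, where PSBW reaches 10502 and PSAE-1 10172.

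All 3 endosperm regulators tested were also higher there, and so when adjusted over the list alone. MPC, an imprinted gene expressed from the maternal copy, was higher by 4.46 (SE 0.43, 4932 ± 395), AGL62 by 3.48 (SE 0.38, 4457 ± 1102) and IKU1, a regulator of endosperm growth, by 1.48 (SE 0.46, adjusted p = 0.0238). AGL62 and IKU1 had higher means in the chalazal endosperm, at 6160 ± 437 and 1777 ± 1091. The call for IKU1 was lost in 2 of 17 alternative fits, both with 1 peripheral array left out (range of adjusted p 0.00702 to 0.176). Of 16 type I MADS-box genes, 9 were higher and 1 lower (camera adjusted p = 9.89e-05), with the same counts adjusted over the list alone and AGL28 (3.87, SE 0.41) and AGL46 (3.31, SE 0.46) among them. DFR was the 1 flavonoid gene called lower, by -1.09 (2 adjusted over the list alone), and the cell cycle list had AUR1 higher (2 genes adjusted over the list alone). Both calls were lost in some alternative fits, 4 of 17 for DFR (adjusted p from 0.00263 to 0.520) and 5 of 17 for AUR1 (0.0176 to 0.253). BBM passed as lower only when adjusted over the list alone. The total of 3719 dropped to 1662 and 1846 without peripheral endosperm replicate 1 and replicate 2.

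The chalazal endosperm had the most calls of any compartment, with 2117 probe sets higher than the mean of the other 5 and 3246 lower. SBT4.13, a subtilase, was higher by 8.82 (SE 0.52, adjusted p = 4.77e-10), at 36579 ± 8075 against 5.46 ± 2.98 in the peripheral endosperm. AT3G03410 reached 105314 ± 12504 and was higher by 8.39 (SE 0.61). The genes AT3G05860 (5.47, SE 0.43, 12167 ± 2112), AT4G36590 (4.54, SE 0.44, 9772 ± 524) and AT5G26630 (4.51, SE 0.40, 12069 ± 2665), all of the type I MADS-box list, were higher with AGL62 (4.06, SE 0.38, 6160 ± 437). OTC, the ornithine transcarbamylase of arginine synthesis, was lower by -4.22 (SE 0.50).

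Of the 16 type I MADS-box genes, 9 were higher and 1 lower, the same adjusted over the list alone, with a median of 1.98 (camera adjusted p = 0.000172). Of the 16, 8 had their brightest compartment mean in the chalazal, 4 in the micropylar and 3 in the peripheral endosperm. The cell cycle genes went the other way, with all 3 lower, AUR1 by -2.85 (SE 0.49, 18.1 ± 1.22) and PRL by -1.88 (SE 0.34). AUR2 lost its call in 11 of 17 alternative fits (range of adjusted p 0.00313 to 0.786). Of 7 photosynthesis genes 2 were lower and the set was not called against other genes (camera adjusted p = 0.336). The median over all tested probe sets was -0.25, the furthest from 0 of any comparison, and the replicates were the loosest of any group. The total of 5363 dropped to 3339 without chalazal endosperm replicate 2.

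In the general seed coat, 2293 probe sets were higher than the mean of the other 5 compartments and 1399 lower. THI2.1, a thionin of plant defence, was higher by 7.35 (SE 0.61, adjusted p = 3.50e-08) and reached 50005 ± 6854, against 9546 ± 3495 in the chalazal seed coat. A thiol reductase of the GILT family (GILT) was higher by 6.44 (55699.9 ± 14016) and the peroxidase PRXR1 by 6.17 (12044 ± 1704). DFR was higher by 3.53 (SE 0.32, 29398 ± 3999) and BAN by 3.62 (SE 0.47, 6474 ± 3304). AT5G40155 was lower by -4.56 (SE 0.35).

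Both tested genes of the seed coat list were higher, ARA12 by 3.72 (SE 0.48) and INO, a YABBY transcription factor of the outer integument, by 2.71 (SE 0.46, 643 ± 169). With DFR and BAN, 2 of 3 flavonoid genes were higher. YUC6 was higher by 2.84 (SE 0.49). Of 16 type I MADS-box genes, 8 were lower and none higher, and 11 were lower adjusted over the list alone (median -1.67, camera adjusted p = 2.79e-07). Of 7 photosynthesis genes, 3 were lower, with a camera adjusted p of 0.0112 that became an adjusted p = 0.0580 with an estimated correlation. AGL62 and MPC were lower among the endosperm regulators, and all 3 were lower adjusted over the list alone, while RR22 was lower (both cytokinin genes adjusted over the list alone). The calls of MPC and RR22 were lost in 3 and 8 of 17 alternative fits (adjusted p from 0.00670 to 0.237 and from 0.0111 to 0.667). The total of 3692 dropped to 1883 and 2277 without general seed coat replicate 1 and replicate 2.

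The chalazal seed coat was higher than the mean of the other 5 compartments for 2682 probe sets and lower for 1719. RR22 (ARR22), a response regulator that acts in cytokinin signalling, was higher by 7.09 (SE 0.58, adjusted p = 1.63e-08), at 17021 ± 638 against 104 ± 122 in the general seed coat. The homeodomain gene HAT2 was higher by 6.51 (SE 0.53) and SWEET10, a sugar transporter, by 6.42 (SE 0.51, 5338 ± 2206). YUC6 was higher by 3.74 (SE 0.49, 1279 ± 622), and DFR and BAN were higher by 2.21 (SE 0.32) and 2.73 (SE 0.47). AT2G02515 was lower by -6.77 (SE 0.27), TBL42 by -6.11 and LCR24, a small cysteine-rich peptide, by -5.84.

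Of 16 type I MADS-box genes, 9 were lower (10 adjusted over the list alone) and 1 was higher, AT1G17310 by 2.35 (SE 0.43), with a camera adjusted p of 4.66e-05. Of 7 photosynthesis genes 5 were lower, also adjusted over the list alone (camera adjusted p = 0.000224). MPC and AGL62 were lower by -3.77 (SE 0.43) and -2.80 (SE 0.38), the 2 calls among 3 endosperm regulators. In the cell cycle list 2 of 3 were lower, AUR2 and AUR1. Each of these calls was lost in 1 of 17 alternative fits, with an adjusted p of 0.177 for AUR2 without chalazal seed coat replicate 1 (range 0.000173 to 0.177) and of 0.298 for AUR1 without replicate 2 (range 0.00296 to 0.298). ARA12 had a difference of 1.33 that was lost in 12 of 17 fits (range of adjusted p 0.00396 to 0.390). BBM passed as lower and PHV as higher only when adjusted over the list alone. Quantile normalization moved the median of all probe sets here from 0.04 to -0.08. The total of 4401 dropped to 2589 without chalazal seed coat replicate 1 and to 2460 without replicate 2.

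**Figure D4:**
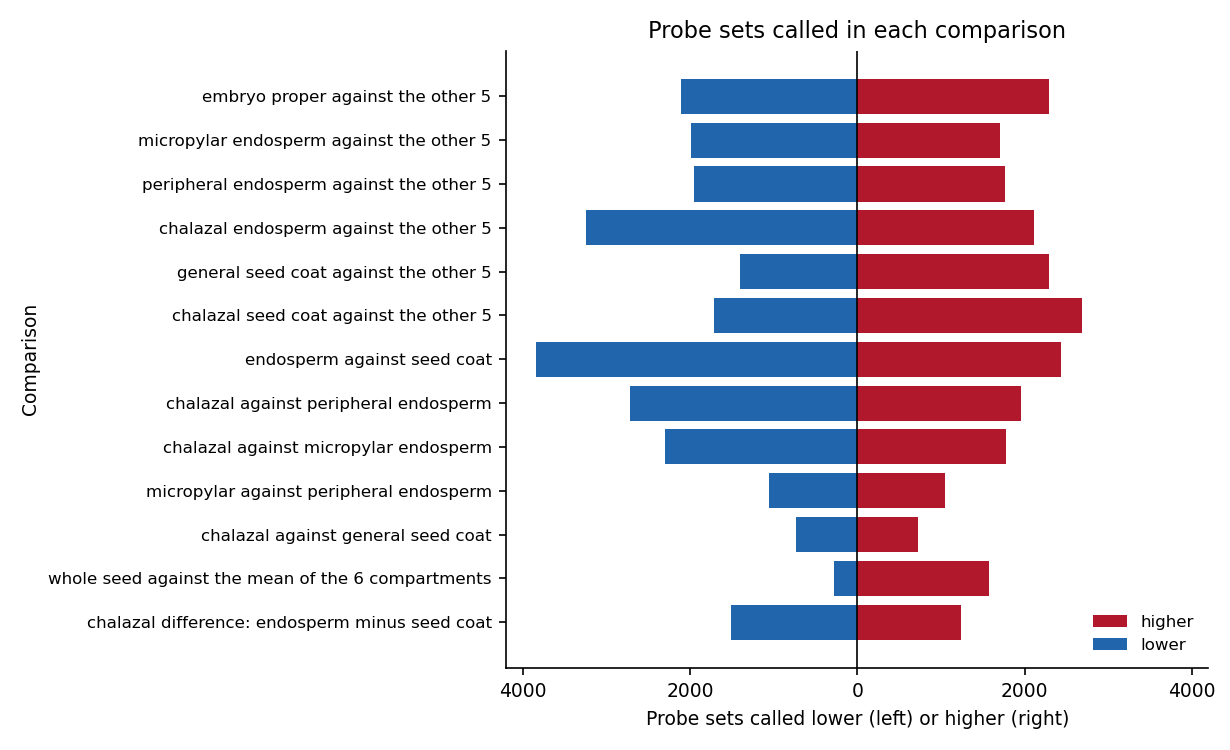
Bars give the number of probe sets called lower (left) and higher (right) in each of the 13 comparisons, out of 17336 tested. The chalazal endosperm leads among single compartments with 2117 higher and 3246 lower, and the whole seed has 1575 higher and 285 lower.

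A stricter count asked for probe sets higher than in each of the other 5 compartments taken singly. It gave 608 in the chalazal endosperm, 332 in the embryo proper, 327 in the micropylar endosperm, 322 in the chalazal seed coat, 319 in the general seed coat and 217 in the peripheral endosperm. The counts lower than in each other compartment were 448, 140, 79, 79, 23 and 46 in the same order. These counts moved with several choices. The higher count of the embryo proper dropped to 159 and 143 without embryo proper replicate 1 and replicate 2, that of the peripheral endosperm to 80 and 79 without its replicates 1 and 2, and that of the chalazal seed coat to 203 and 197 likewise. For the general seed coat the count was 186 and 187 without its own replicates 1 and 2 and 198 without chalazal seed coat replicate 2. Without a pseudocount the 6 counts were 383, 143, 190, 126, 129 and 109, in the order given first.

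Endosperm and seed coat were set against each other as the mean of 3 endosperm regions against the mean of 2 seed coat regions. The endosperm was higher for 2433 probe sets and lower for 3843. AT2G02515 was higher in endosperm by 6.84 (SE 0.23, adjusted p = 2.71e-14), with 80897 ± 11939 in the micropylar endosperm and 26.6 ± 0.498 in the chalazal seed coat. TBL42 was higher by 6.81 (SE 0.29), LCR24 by 6.27 (SE 0.23) and AGL62 by 4.64 (SE 0.32). PRXR1 was lower in endosperm by -6.94 (SE 0.33), THI2.1 by -6.90 (SE 0.51) and bZIP44, a transcription factor, by -6.74 (SE 0.37).

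Type I MADS-box genes were higher in endosperm in 14 of 16 cases and lower in none, also adjusted over the list alone, with a median of 2.05 (camera adjusted p = 3.12e-08). Photosynthesis genes were higher in 6 of 7 cases (camera adjusted p = 2.72e-05), with the same count adjusted over the list alone. All 3 endosperm regulators were higher, including MPC by 3.90 (SE 0.36) and IKU1 by 1.67 (SE 0.38). The flavonoid genes DFR and BAN were lower in endosperm by -3.01 (SE 0.27) and -3.61 (SE 0.39), ARA12 was lower by -3.47 (SE 0.40) and RR22 by -3.15 (SE 0.48). For RR22 the difference rested on the chalazal seed coat (17021 ± 638). Its mean was 104 ± 122 in the general seed coat, and 170, 133 and 134 in the micropylar, peripheral and chalazal endosperm. YUC6 was lower (-4.07, SE 0.40) and YUC11 higher (1.34, SE 0.36), and 1 of 3 cell cycle genes, PRL, was lower. YUC11 was bright mainly in the micropylar endosperm (442 ± 158), against 92.2 ± 30.0 in the peripheral and 81.9 ± 15.8 in the chalazal endosperm. The difference of PRL was -0.97 without general seed coat replicate 1, under the 2-fold limit. Quantile normalization moved the median over all probe sets from -0.06 to 0.06. Ratios of control probe sets along 1 transcript, a measure of RNA quality, also differed. The 3' to middle ratio of actin was 3.89 to 5.81 on endosperm arrays and 6.22 to 8.79 on seed coat arrays. The 3' to 5' ratio of GAPDH was 0.89 to 1.49 and 1.55 to 1.92. That of ubiquitin overlapped, at 4.59 to 6.30 and 5.18 to 8.04. Their part in the differences was not tested.

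The 3 endosperm regions also differed among themselves. Between the chalazal and the peripheral endosperm, 1955 probe sets were higher and 2715 lower in the chalazal region. SBT4.13 was higher by 9.77 (SE 0.67) and AT3G03410 by 9.70 (SE 0.79), with ranges of 9.39 to 12.81 and 8.39 to 11.01 over 9 alternative fits. All 7 photosynthesis genes were lower in the chalazal region, also adjusted over the list alone (camera adjusted p = 2.10e-06), with PSAN at -5.18 (SE 0.69) and PSBW at -2.72 (SE 0.32). Of 16 type I MADS-box genes 4 were higher and 2 lower (3 lower adjusted over the list alone), with AGL91 at 3.74 (SE 0.65) and AGL46 at -3.40 (SE 0.59), and the list did not move as a whole (camera adjusted p = 0.321). AGL62 was not called between these regions (0.48, SE 0.49, adjusted p = 0.503). MPC was lower by -3.61 (SE 0.55), and AUR1 by -3.60 (SE 0.63) with 1 other cell cycle gene, AUR2 (all 3 adjusted over the list alone). The call for AUR2 was lost in 3 of 9 alternative fits (adjusted p from 0.00123 to 0.272). The total of 4670 dropped to 3008 and 3109 without peripheral endosperm replicate 1 and replicate 2.

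Between the chalazal and the micropylar endosperm, 1781 probe sets were higher and 2302 lower in the chalazal region. RALFL28, of a family of secreted signalling peptides, was higher by 8.37 (SE 0.56), at 25539 ± 635 against 42.0 ± 12.3. AT3G05860 was higher by 5.84 (SE 0.55) and AGL62 by 2.82 (SE 0.49), while AGL96 was lower by -5.81 (SE 0.64), AGL57 by -5.38 (SE 0.59) and AGL48 by -5.03 (SE 0.57). Both regions had looser replicates and brighter control spots than the others. The total of 4083 was 2380 with array weights and 1848 in a fit of these 2 groups alone.

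Between the micropylar and the peripheral endosperm, 1049 probe sets were higher and 1062 lower in the micropylar region. AT4G23080 was higher by 7.98 (SE 0.66), AGL57 by 6.43 (SE 0.59), AGL48 by 4.71 (SE 0.57) and AGL96 by 4.40 (SE 0.64). AGL28 was lower by -3.61 (SE 0.53) and RCA by -2.62 (SE 0.49). AGL62 was lower by -2.34 (SE 0.49, adjusted p = 0.00323). That call was lost without peripheral endosperm replicate 2 (adjusted p = 0.0599, the highest of 9 alternative fits, whose lowest was 0.00333). The total of 2111 dropped to 1374 without micropylar endosperm replicate 2 and to 869 and 952 without peripheral endosperm replicate 1 and replicate 2.

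The chalazal and the general seed coat differed for fewer probe sets, with 724 higher and 731 lower in the chalazal region. AT3G10590 was higher by 8.44 (SE 0.74), at 13924 ± 63.8 against 4.22 ± 0.627, and by 8.43 to 11.70 over 9 alternative fits, the largest without a pseudocount. AT4G22050 was higher by 8.32 (SE 0.57), AT1G12180 by 7.83 (SE 0.64) and RR22 by 7.28 (SE 0.75). AT1G49800 was lower by -7.56 (SE 0.59), with 9237 ± 615 in the general seed coat. INO was lower by -2.73 (SE 0.59), the 1 of 2 seed coat genes called (both adjusted over the list alone), and its call was lost in 3 of 9 alternative fits (adjusted p from 0.00162 to 0.0772).

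No flavonoid or cell cycle gene was called between the seed coat regions, and 1 and 2 respectively were lower adjusted over the list alone. Of 16 type I MADS-box genes 1, AT1G17310, was higher, also adjusted over the list alone (camera adjusted p = 0.417), and its call was lost in 2 of 9 alternative fits (adjusted p from 0.00115 to 0.0631). None of 7 photosynthesis genes was called (camera adjusted p = 0.106), 1 endosperm regulator, MPC, was lower, and that call was lost in 4 of 9 alternative fits (adjusted p from 0.00186 to 0.199). The total of 1455 was 875 without a pseudocount, 877 and 811 without chalazal seed coat replicate 1 and replicate 2, and 879 and 902 without general seed coat replicate 1 and replicate 2.

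The chalazal step was also compared between endosperm and seed coat through the interaction, that is, the chalazal minus peripheral endosperm difference less the chalazal minus general seed coat difference. It was above 0 for 1237 probe sets and below 0 for 1506. AT3G01880 had an interaction of 7.95 (SE 0.84), with 17239 ± 5538 in the chalazal endosperm and 166 ± 106 in the chalazal seed coat. RR22 (-7.37, SE 1.06), the sucrose phosphate synthase gene ATSPS4F (-7.34, SE 0.87) and AT1G26450 (-6.58, SE 0.87) went the other way. Of the probe sets called in both tissues, 203 were higher on the chalazal side of both and 168 lower in both, and their differences could be unequal in size. AT1G12180, AT4G22050 and AT3G10590 were among those higher in both, at 62657 ± 9184, 12488 ± 3417 and 27409 ± 5054 in the chalazal endosperm. The interaction total of 2743 was 1782 without a pseudocount, 1719 without peripheral endosperm replicate 1 and 1767 without chalazal seed coat replicate 2.

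**Figure D5:**
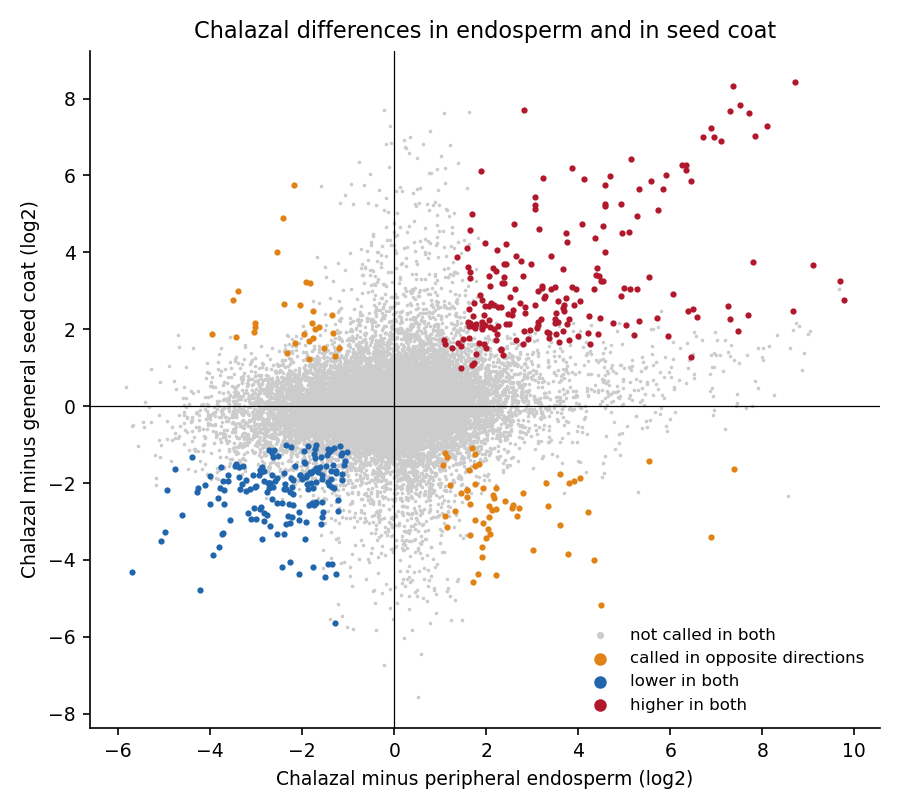
Each point is 1 of 17336 probe sets, with its chalazal minus peripheral endosperm difference (x axis, log2) and its chalazal minus general seed coat difference (y axis, log2). Coloured points were called in both, 203 higher in both, 168 lower in both and 87 in opposite directions.

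The whole seed was set against the mean of the 6 compartments on the log2 scale and was higher for 1575 probe sets and lower for 285. AT4G12890 was higher by 5.30 (SE 0.48, adjusted p = 6.77e-07), at 15279 ± 2255 against 2872 ± 2255 in the chalazal seed coat, the brightest compartment. GH3.3, an enzyme that conjugates auxin, was higher by 4.90 (SE 0.79, 3674 ± 548) and the metallothionein MT1C by 4.56 (SE 0.55). Genes that were bright in the seed coat were also higher in the whole seed, namely RR22 by 4.59 (SE 0.57), ARA12 by 2.91 (SE 0.48) and DFR by 2.42 (SE 0.32). AT3G19360 was lower by -2.39 (SE 0.39) and AT1G13160 by -2.12 (SE 0.31).

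Of the 16 type I MADS-box genes none was called in the whole seed (camera adjusted p = 0.106). Of 7 photosynthesis genes 1 was higher, with a camera adjusted p of 0.0409 that became an adjusted p = 0.108 with an estimated correlation. That gene, PSAE-1, lost its call in 10 of 19 alternative fits (adjusted p from 0.0185 to 0.731). The flavonoid list had 2 of 3 higher and the seed coat list 2 of 2. BAN and INO lost their calls in 1 fit each, BAN without whole seed replicate 2 (adjusted p = 0.121, with a range of 0.000249 to 0.121) and INO without replicate 1 (adjusted p = 0.188, with a range of 0.00226 to 0.188). The auxin list had 1 of 4 higher, YUC6, whose call was lost in 3 of 19 fits (adjusted p from 0.00366 to 0.108), and the cytokinin list 1 of 2. PHV passed as higher only when adjusted over the list alone. No cell cycle gene, endosperm regulator or heat shock gene was called.

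In the whole seed 6 probe sets were higher than in each of the 6 compartments, and 1 was lower. The count of 6 was 0 without a pseudocount, 10 with array weights, 11 with the replicate block, 1 without chalazal seed coat replicate 2 and 2 without either general seed coat or either whole seed array. Among the 6, AT4G12890 and AT5G63180 (1781 ± 604 in the whole seed, 141 ± 7.31 in the general seed coat) were named by the rule. AT4G02450, named after its values were seen, was the 1 lower gene, at 2611 in the whole seed and 5512 to 16186 in the compartments (means of log2 values turned back to signal). Quantile normalization gave 1302 higher and 459 lower in the whole seed, a share of higher calls of 73.9% against 84.7%, and moved the median over all probe sets from 0.09 to -0.09. The total of 1860 was 1141 without a pseudocount, 613 without whole seed replicate 1 and 624 without replicate 2.

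The set tests for the type I MADS-box and photosynthesis lists formed a family of 20, and 14 were called. With a correlation estimated from the data in place of the preset value, 12 of the 14 calls held, and those for photosynthesis genes in the general seed coat and the whole seed were the ones lost.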

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

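The comparison of the chalazal differences in endosperm and seed coat was planned, and of the tests in this part the spread of the seed coat to endosperm ratio, over all shared probe sets and over the strongest, was chosen only after the result was seen.

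The chalazal difference in endosperm differed from that in seed coat, by the interaction test, for 2743 probe sets. Among the genes named by the rule, the interaction was 8.35 for AT2G45840, 8.08 for AT1G49800, 7.95 for AT3G01880, 7.77 for AT5G47550, 7.43 for AT1G30710 and 7.43 for AT1G53400. On the other side it was -7.37 for RR22, -7.34 for ATSPS4F, -7.11 for AT5G54660, -6.99 for LCR68, -6.72 for AT4G20320 and -6.58 for AT1G26450. The call of each of these 12 genes held in the 13 alternative fits, while the sizes did not, since without a pseudocount the interaction was -12.05 for AT4G20320, -9.97 for AT1G26450, 10.81 for AT2G45840 and 9.93 for AT1G53400.

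List members also differed between the tissues. The interaction was 3.54 for AGL91, -2.95 for AGL29, 2.62 for AT5G26630 and -2.96 for AGL46 among type I MADS-box genes. It was 2.14 for DFR, 3.18 for INO, -2.81 for PSBW, -3.31 for RCA, -2.03 for PSBY and -3.13 for PSAN. Of 13 alternative fits, the call was lost in 2 for AGL91, 5 for AGL29, 4 for AT5G26630, 6 for AGL46, 5 for DFR, 3 for INO and 10 for PSAN.

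A control probe set for 25S ribosomal RNA, outside the tested values, had a mean of 181756 in the micropylar and 120744 in the chalazal endosperm, above the 65818 of the whole seed. The spike-in means were also higher on these arrays, at 86690 and 66748 against 37943 in the whole seed. The scaling of the arrays was therefore not told apart from a tissue difference.

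Beside these differences, 203 probe sets were higher on the chalazal side of both endosperm and seed coat, where independent lists would share 81.6, and 168 were lower in both (114 for independent lists), although the comparisons share no arrays. Tissue of one chalazal compartment caught with the other is argued against as the whole cause, in both directions. The share that the donor's abundant genes allowed, as their 25th percentile, was 0.289% for chalazal endosperm in seed coat and 0.696% for the reverse. Over 3 times that share was needed by 99.0% and 99.5% of the 203 probe sets. Probe sets dim in the donor had to pass that bar to be called, so these percentages alone do not decide. The median share needed was 74.6% and 101%, against a median of 1.17% and 3.67% over the donor's abundant genes. Caught tissue stays open for some shared genes, such as AT3G03410, at 105314 in the chalazal endosperm and 1612 in the chalazal seed coat. A single further tissue caught with both would keep its genes in 1 ratio, and the SD of the log2 ratio over the shared probe sets was 4.62 times that from replicates (3.49 times as a robust SD), which argues against it as the whole cause. For the 20 probe sets ranked highest by the smaller of the 2 differences the SD was 1.43 times that from replicates (1.37 as a robust SD). In the same ranking it was 2.55 times (1.19) for the top 10, 3.74 times (1.53) for 50 and 4.42 times (2.25) for 100. It was 5.16 times (1.25) for the 20 ranked by the sum and 6.54 times (7.74) for the 20 ranked by the larger difference. These rankings use the differences that make up the ratio. The smaller difference favours even ratios and the larger difference uneven ones, so the ranked values do not decide. A further tissue stays open for part of the shared genes, as does expression shared by the tissues of the chalazal pole, which was not tested. AT3G10590, first by the smaller difference, and TET9 were among the shared genes, with differences of 8.72 and 4.59 in endosperm and 8.44 and 5.26 in seed coat.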

How the results depend on the processing

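The fit without all micropylar and chalazal endosperm arrays was chosen after the spread of the replicates was seen, and the other alternatives were planned. The 20 counts stayed within 1.5 times their value under quantile normalization, without the trend and without the filter. Without a pseudocount 10 moved: the chalazal against the general seed coat gave 875, the whole seed 1141 and the interaction 1782. The counts higher than each other compartment were then 143 (embryo proper), 190 (micropylar), 109 (peripheral) and 383 (chalazal endosperm), 129 (general) and 126 (chalazal seed coat), and 0 for the whole seed. Array weights, at 0.575 for chalazal endosperm and 1.40 for embryo proper arrays, gave 2380 for the chalazal against the micropylar endosperm and 10 for the whole seed above each compartment. Only the groups compared in the fit gave 1848 for the chalazal against the micropylar endosperm, with fewer arrays. The cause was not tested for the counts that moved without a pseudocount or with weights. Without all micropylar and chalazal endosperm arrays, the counts higher than each other compartment were 598 (embryo proper), 870 (peripheral endosperm), 505 (general) and 643 (chalazal seed coat). Fewer comparisons then had to be passed, and the groups with the loosest replicates no longer entered the spread. These were not told apart.

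The replicate numbers did not pair the arrays, as correlations of deviations over 21 pairs of groups ran from -0.028 to 0.043. The replicate block gave 11 for the whole seed above each compartment, left the other 19 counts within 1.5 times their value and kept the 311 calls of named genes and 14 list calls.

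With each array left out in turn, where a lone array was assumed to vary like the other groups, the count ranged from 2065 to 4742 for the embryo proper, 2108 to 4050 for the micropylar, 1662 to 4095 for the peripheral and 3339 to 5590 for the chalazal endosperm, 1883 to 4084 for the general and 2460 to 4754 for the chalazal seed coat. It ranged from 5611 to 6458 for endosperm against seed coat, 3008 to 4433 for the chalazal against peripheral, 3151 to 4005 for the chalazal against micropylar and 869 to 1677 for the micropylar against peripheral endosperm. It ranged from 811 to 902 for the chalazal against general seed coat, 613 to 2247 for the whole seed and 1719 to 3133 for the interaction. For the stricter counts it was 143 to 364 (embryo proper), 226 to 323 (micropylar), 79 to 259 (peripheral), 441 to 562 (chalazal endosperm), 186 to 337 (general), 197 to 324 (chalazal seed coat) and 1 to 9 (whole seed). The whole-seed count of 6 was 1 without chalazal seed coat replicate 2 and 2 without either general seed coat or either whole seed array. In all, 37 of 206 such counts moved, and fewer arrays are part of the construction.

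Of 14 called list tests, all kept their call with fry, without a pseudocount, with quantile normalization and with the block. With an estimated correlation the photosynthesis list lost its call in the general seed coat (adjusted p = 0.0580) and the whole seed (adjusted p = 0.108), and the cause was not tested. Of 311 calls of named genes, 249 held in every refit, 62 were lost in at least 1 and none reversed. Lost calls numbered 28 without a pseudocount, 14 without the trend, 12 with array weights and 8 with quantile normalization, and 169 of 2926 refits with an array left out lost one. Signal near the array background limits dim genes, whose differences depend on the pseudocount.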

Other observations

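The gene families in this part were formed after the probe annotation was seen. Among the tests of explanations, those on the balance of directions, on the seed coat share and on micropylar genes in the embryo proper were chosen only after the result was seen, and the wording of the mixture test was narrowed to the probe sets called higher after its result was seen.

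Of 69 tested chloroplast-encoded genes, 28 were brightest in the micropylar, 41 in the peripheral and 0 in the chalazal endosperm. Of the 69, 46 were higher and none lower in the peripheral endosperm (camera adjusted p = 1.53e-36), and 34 were higher in the micropylar endosperm (camera adjusted p = 1.04e-24). Both calls were lost when the correlation was estimated, with an adjusted p = 0.0986 and an adjusted p = 0.112 with an estimated correlation. psbA, which encodes a core protein of photosystem II, had a signal of 47402 in the micropylar and 30754 in the peripheral endosperm, against 7307 in the embryo proper. Of 8 autophagy genes (ATG), 6 were higher in the chalazal endosperm (camera adjusted p = 0.00101, and adjusted p = 0.227 with an estimated correlation), and ATG8D was higher by 3.13 (SE 0.34).

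Of 8 tested sugar transporters of the SWEET family, 2 were brightest in the micropylar endosperm, 1 in the peripheral endosperm, 2 in the general and 3 in the chalazal seed coat. SWEET8 was higher by 4.36 in the micropylar endosperm (SE 0.37), SWEET4 by 4.66 in the chalazal seed coat (SE 0.53) and SWEET1 by 3.50 in the general seed coat (SE 0.48). In the whole seed 6 of 8 were higher (camera adjusted p = 0.00134, and adjusted p = 0.147 with an estimated correlation). Among tetraspanins, membrane proteins of the TET family, TET4 was higher by 7.41 (SE 0.63) and TET8 by 3.58 (SE 0.37) in the chalazal endosperm, and TET5 by 4.90 (SE 0.44) in the chalazal seed coat. TET9 was higher by 4.02 in the chalazal endosperm and by 3.69 in the chalazal seed coat. These genes were chosen after their values were seen.

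The difference between endosperm and seed coat was set against other splits of their 10 arrays. With 1 mean for each side, the real split called 3094 probe sets and the highest of the other splits 211, and 1 of 100 splits drawn from 210, the real one, gave as many. Most of these splits part the replicates of a group. Of the 10 splits that keep replicates together, the highest of the others called 1630, and 10 splits are too few for a share under 0.05.

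The whole seed had 1575 probe sets higher and 285 lower than the mean of log values of the compartments. An equal mixture of the compartments, set against a mean of logs, is argued against as the whole cause for the probe sets called higher. Of these, 62.5% stayed at least 2-fold above the arithmetic mean, which gives each compartment the same weight. In 20 simulated equal mixtures with array noise, called and chosen in the same way, at most 7.87% did so. A mixture with unequal shares was not tested and stays open. For the balance of directions, setting a mixture against a mean of logs also stays open. Of the probe sets 2-fold off the arithmetic mean 31.3% lay above it, but that mean is never below the mean of logs, so the share had to fall. Of the higher probe sets, 10.5% lay above all 12 compartment arrays. Tissue outside the 6 compartments is only part of a section, so its genes need not pass that limit. The share therefore does not decide on such tissue, which stays open. More seed coat in the section than its 2 of 6 compartments also stays open. A seed coat compartment was the brightest for 89.8% of the higher probe sets. The same share over all tested probe sets was not computed, so this value alone does not decide.

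Micropylar endosperm genes were also seen in the embryo proper, where the median signal of 140 of them was 7.77% of the micropylar level. It was 7.91% in the peripheral endosperm, 4.74% in the chalazal endosperm, 6.30% in the whole seed, 1.27% in the general seed coat and 0.822% in the chalazal seed coat. These 140 were called higher in the micropylar endosperm than in each other compartment except the embryo proper, with a micropylar signal over 5000. The embryo signal was 4.80 times that of the general seed coat. That choice limited the seed coat and not the embryo, so this ratio does not decide on background of the array. The median embryo signal of 1116 lay above the 75th percentile of all non-control values on both embryo arrays (491 and 479). Micropylar tissue caught at 1 share, with no other signal, is argued against. The robust SD of the log2 ratio was 2.60 times that from replicates (2.90 times as a plain SD). For the peripheral endosperm the robust SD was 4.85 times. No baseline was subtracted, which can widen these ratios. In the embryo proper 135 of the 140 genes lay over 2% of the micropylar level, with a 25th percentile of 4.94%. The count and percentile were 113 and 2.53% in the peripheral and 102 and 1.93% in the chalazal endosperm. The choice of the 140 limited the other 2 endosperm regions and not the embryo proper, which can raise the values there. A caught share may still be part of the signal in the embryo proper, and expression of these genes in the embryo stays untested.

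The share of higher calls was 39.5% in the chalazal and 46.2% in the micropylar endosperm, and 45.0% and 46.0% with quantile normalization.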
